A study of Homo sapiens with 6 samples.

How the data were processed

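Polyadenylated RNA of cells labelled as MHCC97-H was sequenced in 6 libraries, 2 each of untreated cells, cells given 40 µM chloroquine for 16 h and cells given 0.2 mM melatonin for 16 h. The deposited table holds integer counts of reads per Ensembl gene for 62710 genes, which the authors made from reads trimmed with fastp and mapped to GRCh38 per the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Library totals ran from 15993730 to 23311452. A count of 0 allows up to 3 counts, and intervals and floors of this kind cover counting error only. Symbols were found for 62706 genes, and 58274 were placed by GENCODE release 29, from which coordinates, transcript length and GC content were taken.

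Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 16877 genes that passed filterByExpr were scaled by TMM factors, and a quasi-likelihood fit (glmQLFit, glmQLFTest, robust dispersion off) of all 6 libraries with 1 term per group gave the comparisons of chloroquine with untreated, melatonin with untreated and chloroquine with melatonin. The common biological coefficient of variation was 0.0315, with 3 residual and 23.6 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. CPM in the text are normalised by the TMM factors, and principal components used log2 CPM with a prior count of 2. The SE of a fold change was taken from the F statistic. Within a group the 2 libraries differed by more than counting error, with a chi-square per degree of freedom of 2.36, 1.83 and 2.65 for untreated, chloroquine and melatonin. Deviations of libraries with equal numbers were not correlated between groups (-0.0168, -0.00876 and -0.0405), so the numbers were not taken as pairs.

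The comparisons, the test, the gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The 38 lists hold genes of both arms of the unfolded protein response, autophagy, lysosome, endosomes, cholesterol synthesis, fatty acid synthesis, cholesterol efflux, fatty acid oxidation, glycolysis and hypoxia, NRF2, iron, metallothioneins, p53, apoptosis, DNA replication, mitosis, hepatocytes, epithelial-mesenchymal transition, NF-kB, interferon, immediate early response, YAP, heat shock, proteasome, oxidative phosphorylation, circadian clock, melatonin receptors and metabolism, and phosphoinositides and sphingolipids. They also hold ribosomal proteins, mitochondrially encoded, non-polyadenylated and nuclear-retained RNAs, and markers of fibroblasts, leukocytes, endothelium, cholangiocytes and red blood cells. Lists with at least 3 measured members (36 of them) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists of a comparison. With an estimated correlation, camera takes its p-values on the 3 residual degrees of freedom. A call can therefore be lost there whatever the correlation between the genes. Camera compares a list with the other genes and fry with no change, so ranges of a list over alternatives are those of camera. Members were also counted at p-values adjusted over the list alone.

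Named genes were the 10 highest and 10 lowest fold changes of each agent among called genes with an average log2 CPM of at least 2, a symbol that is no clone name and groups that do not overlap. With them came up to 4 members with the smallest p of each primary list, up to 2 of each other list, and 31 genes of ER stress, autophagy, lysosome, sterol, growth and liver fixed in advance. The direct comparison took 5 genes at each end, and the overlap 5 for each pattern of direction. MYLIP, CENPE with melatonin, CDKN2A, STK11, and the tubulin and posterior HOX genes in the text outside this rule were chosen after their values were seen, apart from the place that MYLIP has in the overlap.

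The alternative settings fixed then were RLE size factors, upper-quartile factors, library totals only, DESeq2 1.42.0, limma-voom, a robust dispersion, no count filter, a mean count of at least 50, a fit of only the 2 groups compared, the replicate number as a block, a test against a 1.5-fold change, and each library left out. In the last of these a lone library is assumed to vary like the other groups. Chosen after seeing the data were offsets that take out the trend of each library with GC content and transcript length (a local regression with a span of 0.3 on 12627 genes with an average log2 CPM above 1), libraries thinned to equal totals, the offsets together with the block, and a separate untreated library for each agent, without and with the offsets. GC content was known for 16295 tested genes (96.6%).

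The steps were tested on simulated data with 200 changed genes for each agent. At 1.5-fold, 72.3% of the changed genes were called in the simulated chloroquine comparison and 58.3% in the melatonin comparison. Of the calls, 7.64% and 9.03% were false, above the threshold of 0.05. A simulated GC trend was then added, smaller than the observed one and without a trend in length. With it, 568 of 716 chloroquine calls and 3954 of 4098 melatonin calls were false, against 13 of 158 and 6 of 133 with the offsets. Covariance of the fold changes with no effect was taken from 20 simulations that share untreated libraries. All 6 libraries were used and none was left out of the comparisons.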

Results

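Transcript levels were measured by sequencing of polyadenylated RNA in cells labelled as MHCC97-H, a human hepatocellular carcinoma line with high metastatic capacity. The 6 libraries form 3 groups of 2, which were untreated cells, cells given 40 µM chloroquine and cells given 0.2 mM melatonin, with 16 h of treatment. The submitters' description of the design names chloroquine as an inhibitor of autophagy and melatonin as an inhibitor of endoplasmic reticulum (ER) stress. Untreated libraries 1 and 2 held 16716600 and 18514180 counts, chloroquine libraries 20547241 and 19744127, and melatonin libraries 23311452 and 15993730. Of 62710 genes, 33804 had a count in at least 1 library and 16877 passed the count filter. A level of 3 counts, the limit that a count of 0 allows, lay between 0.123 and 0.184 CPM (counts scaled to a common normalised library total) across the libraries, which covers counting error only. The labels do not say whether the 2 libraries of a group come from separate cultures, so every p-value measures only the spread between these libraries. The untreated cells are labelled as given no treatment, and no library is labelled as given a solvent alone. Changes with an agent can therefore not be told apart from effects of a solvent or of handling that came with it.

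The groups separated on the first 2 principal components of log2 CPM. Component 1 held 58.5% of the variance and set melatonin apart, and component 2 held 15.6% and set chloroquine apart from untreated cells. Mitochondrially encoded transcripts took between 4.72% and 5.64% of the counts of each library, and no gene took more than 1.14%. The libraries also differed in their trend with the GC content of the transcripts. Fold changes fell by 0.135 (log2) per 10% GC with chloroquine and by 0.215 with melatonin, while the largest slope between 2 libraries of a group was 0.0179. They were also lower for shorter transcripts. The Spearman correlation with length was 0.169 with chloroquine and 0.207 with melatonin, against at most 0.0366 between 2 libraries of a group. A list of 6 nuclear-retained RNAs, fixed as a sign of RNA fraction or intronic reads, was higher with chloroquine (adjusted p = 5.39e-04, adjusted p = 0.141 with an estimated correlation) and with melatonin (adjusted p = 0.0136, adjusted p = 0.227 with an estimated correlation). With melatonin that call was lost with the GC offsets (adjusted p = 0.0641, range over 12 alternatives 0.00276 to 0.227). Of 43 genes of hepatocyte identity and secretion, 8 were measured and 36 stayed under 1 CPM in every library, with a sum of 1 count for ALB (albumin) and 2 counts for AFP (alpha-fetoprotein) over the 6 libraries. Of 14 cholangiocyte and progenitor markers 11 were measured, among them KRT7, a keratin of ductal epithelia, at 945 ± 40.5 CPM (SD, n = 2) in untreated cells. MTNR1A, a melatonin receptor gene, had at most 1 count per library, a trace under the count filter, and was not tested.

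**Figure D1:**
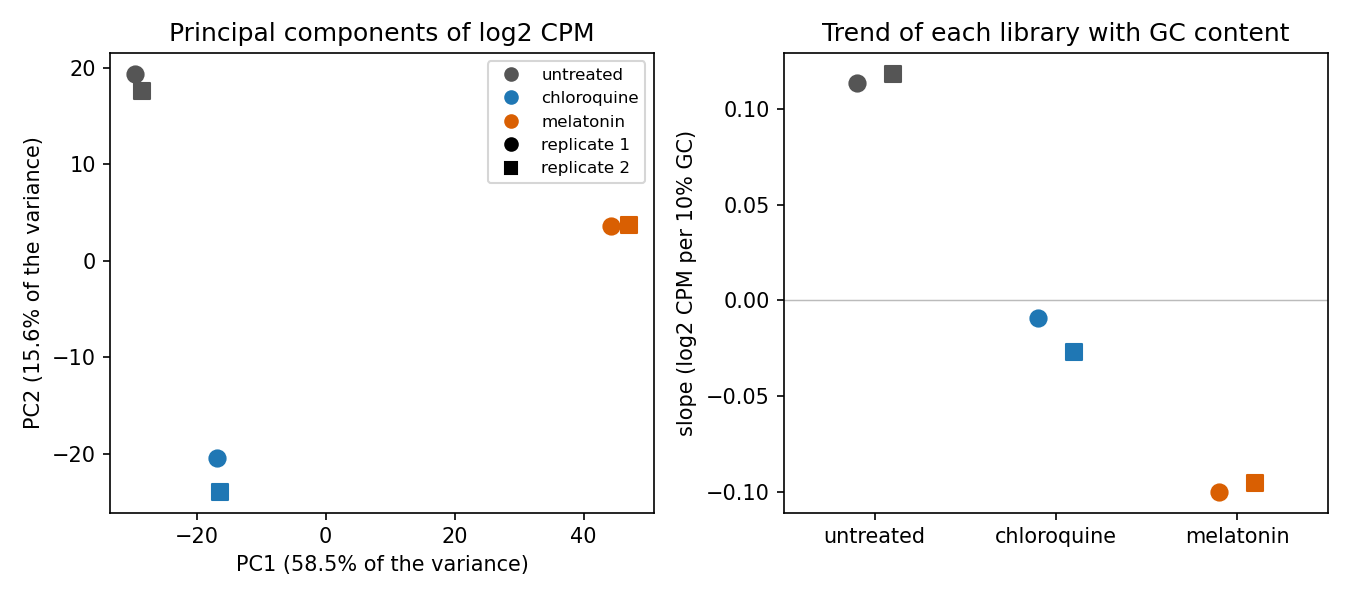
Left, the 6 libraries on principal components 1 and 2 of log2 CPM, with colour for the group and shape for the replicate, where component 1 holds 58.5% and component 2 holds 15.6% of the variance. Right, the slope of each library with GC content (log2 CPM per 10% GC), which was 0.113 and 0.118 in untreated, -0.00916 and -0.0271 in chloroquine and -0.0954 in melatonin library 2, next to which library 1 lies.

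The comparison of chloroquine with untreated cells asked what an inhibitor of autophagy did to transcript levels. Genes of cholesterol synthesis and uptake rose together. Of 28 measured SREBP2 targets, 25 rose and 1 fell over all genes tested, with the same counts of 25 and 1 adjusted over the list alone, and the median log2 fold change was 0.87 (camera adjusted p = 6.33e-205, adjusted p = 0.0148 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate (ENSG00000112972, chromosome 5, 43289395 to 43313512, minus strand, GRCh38), rose 3.68-fold from 119 ± 3.98 to 436 ± 6.45 CPM (SD, n = 2). SQLE, which makes squalene epoxide, rose by 1.40 ± 0.04 (log2, SE), IDI1 by 1.58, MSMO1 by 1.51, INSIG1 by 1.37, LSS by 1.19 and ACAT2 by 1.17. The 1 member that fell was MYLIP (-0.85), an LXR target that encodes a ubiquitin ligase. Of 15 targets of SREBP1 in fatty acid synthesis, 12 rose and 1 fell, as they did adjusted over the list alone (median 0.40, adjusted p = 5.03e-27, adjusted p = 0.0604 with an estimated correlation), with SCD at 0.80 and ACLY at 0.48. Among 8 LXR targets of cholesterol efflux, 4 fell and none rose, also adjusted over the list alone (median -0.21, adjusted p = 2.74e-04, adjusted p = 0.141 with an estimated correlation). The sterol exporters ABCA1 and ABCG1 fell by 1.56 ± 0.17 and by 1.71 ± 0.20, ABCA1 (ENSG00000165029, chromosome 9, 104781002 to 104928237, minus strand) from 9.33 ± 0.590 to 3.15 ± 0.666 CPM (SD, n = 2). Among the 108 list tests of the 3 comparisons, the cholesterol list with chloroquine was the only call that held with an estimated correlation. Calls were also lost in lists whose estimated correlation lay under the preset 0.01, such as endosome genes with chloroquine (-0.0259). Their loss does not show correlation between the genes, since this setting also tests on only 3 degrees of freedom.

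More lysosomal genes rose than fell with chloroquine, and most were not called. Of 71 measured genes of the lysosome and the TFEB network, 24 rose, 9 fell and 38 were not called, or 26 and 9 adjusted over the list alone (median 0.09, adjusted p = 4.6e-06, adjusted p = 0.140 with an estimated correlation). NEU1, a lysosomal sialidase, rose by 1.10 ± 0.06 and GPNMB, a glycoprotein of lysosomes and melanosomes, by 1.20 ± 0.11. NPC1, which exports cholesterol from lysosomes, rose by 0.68, FNIP1 by 0.65 and CTSD by 0.36 (0.60 with the GC offsets), while LAMP1 (0.05, adjusted p = 0.438) and TFEB (-0.22, adjusted p = 0.422) did not pass. Of 57 autophagy genes, 11 rose and 6 fell, with the same counts adjusted over the list alone (median 0.05, adjusted p = 0.0249, adjusted p = 0.201 with an estimated correlation). This call was also lost without untreated library 1 (adjusted p = 0.0578, range over 12 alternatives 0.0132 to 0.201), while fry, which tests against no change, gave adjusted p = 0.0104. SQSTM1, the autophagy receptor p62 (ENSG00000161011, chromosome 5, 179806398 to 179838078), rose from 227 ± 1.61 to 373 ± 8.80 CPM (SD, n = 2), or by 0.72 ± 0.04. RB1CC1 rose by 0.49 and MAP1LC3B by 0.24, GABARAPL1 fell by 0.15 and ULK1 fell by 0.27. ULK1 stood at -0.04 and lost its call with the GC offsets described with the counts, and GABARAPL1 lost its call without chloroquine library 1 (-0.13). BECN1 (-0.03, adjusted p = 0.744) and ATG5 (0.10, adjusted p = 0.289) did not pass. Of 32 genes of endosomes and vesicle traffic, 13 rose and 2 fell, or 15 and 3 adjusted over the list alone (median 0.09, adjusted p = 3.32e-05, adjusted p = 0.140 with an estimated correlation), with EEA1, an early endosome tether, at 0.70.

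ER stress genes went in both directions with chloroquine. Of 36 targets of ATF6 and XBP1, 8 rose and 4 fell, or 9 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.151). HSPA5, the main ER chaperone, stood at 844 ± 20.7 CPM in untreated and 852 ± 13.5 CPM in treated cells (SD, n = 2, log2 fold change 0.01, adjusted p = 0.858), while ERN1 rose by 0.51, SELENOS by 0.31 and XBP1 by 0.28, and HERPUD1 had 0.14 (adjusted p = 0.0503), which passed at 0.14 without melatonin library 2. Of 43 targets of PERK, ATF4 and CHOP, 13 rose and 10 fell, or 15 and 11 adjusted over the list alone, and the list did not pass (adjusted p = 0.160), though it did with the GC offsets (adjusted p = 0.00127, range over 12 alternatives 0.00127 to 0.286). With fry, which tests against no change, the PERK, ATF4 and CHOP list passed upward (adjusted p = 0.0104). DDIT3, which encodes CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), rose 3.05-fold from 7.87 ± 0.379 to 24.0 ± 1.42 CPM (SD, n = 2). PPP1R15A rose by 0.88 and TRIB3 by 0.40, DDIT4 fell by 0.47 and SLC7A5 fell by 0.32 (-0.14 with the GC offsets), and ASNS, asparagine synthetase, had 0.25 (adjusted p = 0.492). ATF4 (0.10), CHAC1 (0.60) and DNAJB9 (0.28) passed in the fit of all libraries, but each lost its call when single libraries were left out. With the GC offsets ATF4 stood at 0.23 and CHAC1 at 0.81, both called, and DNAJB9 at 0.20 without a call. ATF4 stood at 0.08 without untreated library 1, 0.08 without chloroquine library 1 and 0.13 without chloroquine library 2, and CHAC1 at 0.63 and 0.56 without untreated library 1 or 2 and 0.36 without chloroquine library 2. DNAJB9 stood at 0.32 and 0.25 without untreated library 1 or 2 and at 0.34 and 0.23 without chloroquine library 1 or 2.

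With chloroquine more genes rose than fell in the inflammatory and immediate early lists, and more fell than rose in the matrix and glycolysis lists. Of 23 genes of the NF-kB and cytokine list, 10 rose and 2 fell, or 11 and 2 adjusted over the list alone (median 0.23, adjusted p = 4.52e-07, adjusted p = 0.140 with an estimated correlation), with SOD2 at 1.10, CXCL8 at 1.02, PTGS2 at 1.01 and TNFAIP2 at -0.62. Of 35 immediate early and MAPK feedback genes, 15 rose and 4 fell, or 16 and 5 adjusted over the list alone (median 0.22, adjusted p = 0.00512, adjusted p = 0.217 with an estimated correlation), with DUSP4 at 0.99 and ETV5 at 0.74. Of 35 epithelial-mesenchymal and matrix genes, 4 rose and 12 fell, or 6 and 13 adjusted over the list alone (median -0.18, adjusted p = 4.92e-06, adjusted p = 0.140 with an estimated correlation), with TGFBI at -0.77, TNC at -0.67 and COL5A1 at -0.47 (-0.29 with the GC offsets). Of 32 genes of glycolysis and hypoxia, 4 rose and 17 fell, or 4 and 18 adjusted over the list alone (median -0.15, adjusted p = 1.29e-05, adjusted p = 0.286 with an estimated correlation), with SLC16A3, a lactate exporter, at -0.58 (-0.37 with the GC offsets). Of 25 p53 targets, 1 rose and 7 fell, or 1 and 8 adjusted over the list alone (median -0.14, adjusted p = 0.00100, adjusted p = 0.319 with an estimated correlation), with CDKN1A at -0.71 and BTG2 at -0.75. Neither proliferation list passed. Of 40 replication genes 6 rose and 12 fell (6 and 13 adjusted over the list alone, adjusted p = 0.189) and of 37 mitosis genes 8 rose and 3 fell (8 and 5 adjusted over the list alone, adjusted p = 0.189), although the mitosis list passed without untreated library 2 (adjusted p = 0.0499, range over 12 alternatives 0.0499 to 0.893). MKI67 had 0.03 (adjusted p = 0.690) and CCND1 rose by 0.29.

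In all, 3413 genes changed with chloroquine, 1610 upward and 1803 downward, of which 142 changed at least 2-fold (68 up, 74 down), and the median size of the change was 0.27 (log2). Among the largest changes under the naming rule, FBXO32, a ubiquitin ligase subunit, rose by 1.57 ± 0.12. Under the same rule ALPI fell by 1.32, LY6D by 1.11, TNFSF10, the death ligand TRAIL, by 1.08, CHCHD10 by 1.01, PDGFRB, a member of the fibroblast list, by 1.00 and KRT81 by 0.98. H19 fell by 3.01 ± 0.49, but its untreated libraries held 2867 and 586 counts against 215 and 288, it stood at -1.34 without untreated library 1, and it lost its call in DESeq2 and with a robust dispersion. EIF3CL, which shares sequence with EIF3C, fell by 1.45. The count was 2025 in DESeq2, 47 (34 up, 13 down) when tested against a 1.5-fold change, 2249 without chloroquine library 1 and 1974 without chloroquine library 2. With offsets that took out the trend of each library with GC content and transcript length, chosen after seeing the data, 1821 genes were called, and 1361 of the 3413 kept their call. The numbers of called members given above for each list with chloroquine are those without these offsets. The 142 with at least 2-fold were 87 without chloroquine library 2, 29 in DESeq2, 41 at a mean count of at least 50 and 32 when tested against a 1.5-fold change.

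**Figure D2:**
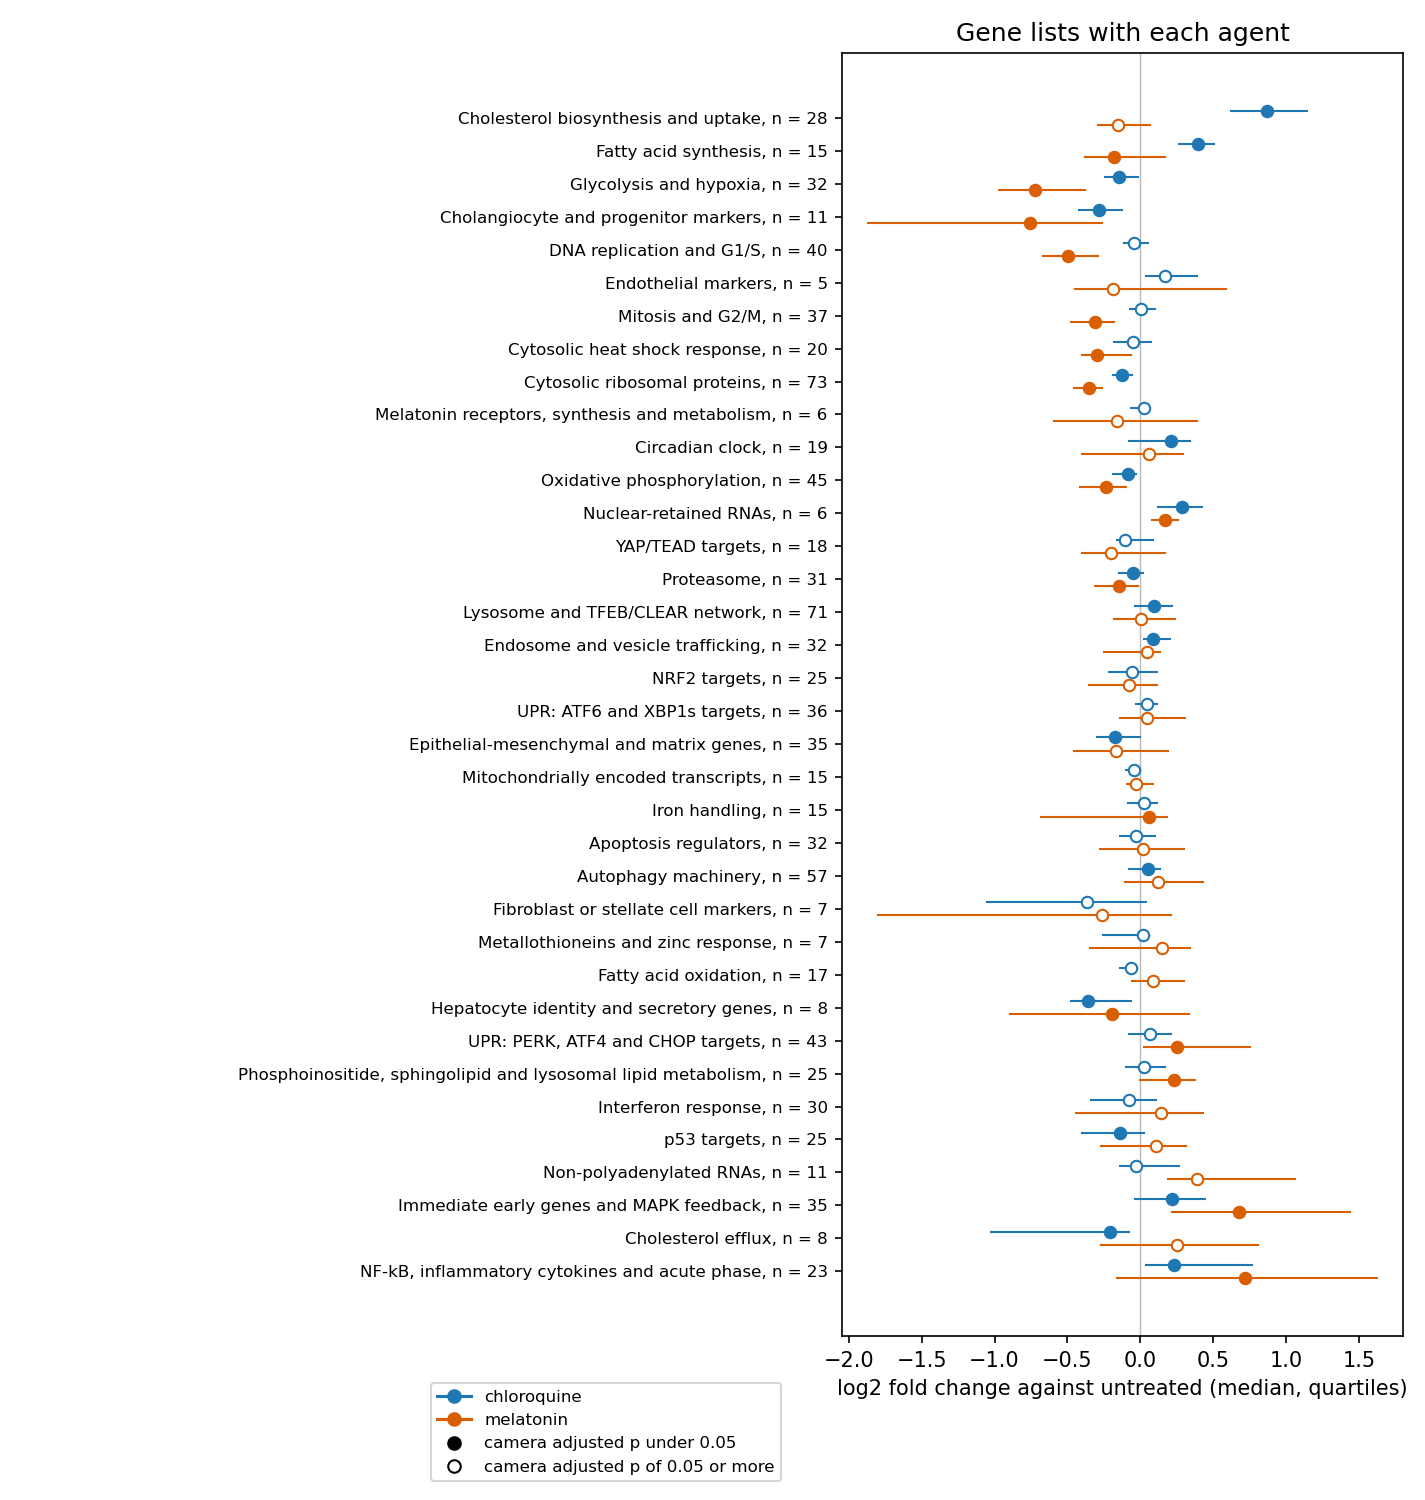
Median (points) and quartiles (lines) of the log2 fold change against untreated cells over the measured members (n) of each gene list with at least 3 of them, for chloroquine in blue and melatonin in orange, with filled points where the camera adjusted p is under 0.05. The cholesterol list stands at 0.87 with chloroquine and at -0.15 with melatonin, and the glycolysis list at -0.15 and -0.72.

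The comparison of melatonin with untreated cells asked what the agent used against ER stress did to transcript levels. Genes of the PERK, ATF4 and CHOP list, fixed as the integrated stress response, rose, while PERK activity itself was not measured. Of 43 measured genes of the list, 30 rose and 7 fell, with the same counts adjusted over the list alone (median 0.25, adjusted p = 1.69e-08, adjusted p = 0.115 with an estimated correlation). CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956519), rose 4.82-fold from 3.17 ± 0.105 to 15.3 ± 0.490 CPM (SD, n = 2) and ASNS rose 3.85-fold from 2.21 ± 0.0877 to 8.49 ± 0.548 CPM. DDIT3 rose 2.78-fold to 22.0 ± 0.789 CPM, SLC7A11, the cystine transporter, by 1.60, ATF3 by 1.44, TRIB3 by 0.76, MTHFD2 by 0.59, PSAT1 by 0.56 and ATF4 by 0.48. Of 36 ATF6 and XBP1 targets, 17 rose and 7 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.0664), though it did without melatonin library 1 (adjusted p = 0.0447, range over 12 alternatives 0.0109 to 0.423). With fry, which tests against no change, the ATF6 and XBP1 list passed upward (adjusted p = 0.0127). ERN1 rose by 0.97, XBP1 by 0.66, DNAJB9 by 0.63, HSPA13 by 0.60, SEL1L by 0.53 and HERPUD1 by 0.40, with HSPA13 at 0.36 and SEL1L at 0.31 under the GC offsets. HSPA5 had 0.06 (adjusted p = 0.142, 882 ± 26.9 CPM) and passed without melatonin library 1 (0.09) and with library totals only (0.16).

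Genes of sugar metabolism and of proliferation fell with melatonin. Of 32 genes of glycolysis and hypoxia, 29 fell and none rose, with the same counts adjusted over the list alone (median -0.72, adjusted p = 4.77e-40, adjusted p = 0.115 with an estimated correlation). GPI, which converts glucose 6-phosphate (ENSG00000105220, chromosome 19, 34359480 to 34402413), fell from 797 ± 9.67 to 333 ± 19.9 CPM (SD, n = 2), and PGK1 fell by 1.03. Of 40 genes of DNA replication and the G1/S transition, 34 fell and none rose, also adjusted over the list alone (median -0.49, adjusted p = 4.37e-21, adjusted p = 0.214 with an estimated correlation), with UHRF1 at -1.25, MCM5 at -0.95, MCM2 at -0.78 and MCM7 at -0.77. Of 37 mitosis genes, 30 fell and 1 rose, also adjusted over the list alone (median -0.31, adjusted p = 5.80e-10, adjusted p = 0.222 with an estimated correlation), with UBE2C at -0.91, PLK1 at -0.74, MKI67 at -0.58 and TPX2 at -0.55. The 1 member that rose was CENPE (0.47), a mitotic kinesin. CCND1 had 0.05 (adjusted p = 0.426) and CDKN1A had -0.09 (adjusted p = 0.124), which turned to 0.14 and passed with the GC offsets and passed at -0.17 without melatonin library 1. Among 45 nuclear-encoded genes of oxidative phosphorylation, 1 rose and 32 fell, or 2 and 34 adjusted over the list alone (median -0.24, adjusted p = 3.85e-06, adjusted p = 0.166 with an estimated correlation), with ATP5MC1 at -0.91. Of 20 heat shock genes, 2 rose and 14 fell, or 3 and 15 adjusted over the list alone (median -0.30, adjusted p = 3.39e-06, adjusted p = 0.166 with an estimated correlation), with HSPB1 at -1.50 and HSPA8 at -0.83.

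Immediate early and inflammatory genes rose more with melatonin than any other list by median. Of 35 immediate early and MAPK feedback genes, 25 rose and 5 fell, also adjusted over the list alone (median 0.68, adjusted p = 4.47e-09, adjusted p = 0.115 with an estimated correlation), with EGR1 at 2.94 ± 0.12, DUSP6 at 2.33 and CCN1 at 1.44. Of 23 NF-kB and cytokine genes, 13 rose and 6 fell, also adjusted over the list alone (median 0.72, adjusted p = 1.3e-06, adjusted p = 0.176 with an estimated correlation). CXCL8, a neutrophil chemokine, rose 9.83-fold from 7.10 ± 0.0181 to 69.8 ± 0.460 CPM (SD, n = 2), PTGS2 rose by 1.51, SOD2 by 0.78, and IL32 fell by 1.41. The largest rise under the naming rule was that of DHRS2, a short-chain dehydrogenase (ENSG00000100867, chromosome 14, 23630115 to 23645639), which rose by 4.93 ± 0.16 (log2, SE) to 39.2 ± 0.885 CPM (SD, n = 2). Its untreated libraries held 12 and 32 counts, and its log2 fold change was 4.46 without untreated library 1 and 5.72 without untreated library 2. AREG, an EGF receptor ligand, rose by 3.37 ± 0.15, CRISPLD2 by 2.71, SERPINI1 by 2.64, PAG1 by 2.56, CLDN1 by 2.55 and CREB5 by 2.40. The largest falls under the naming rule, apart from H19, were those of ALPI (-3.71), CCN5 (-3.16), BIRC7 (-3.09), ACTC1 (-2.74), SERPINB3 (-2.71), CP (-2.68), SERPINB4 (-2.56), CASP14 (-2.53) and GAS6-AS1 (-2.49). H19 had -2.89, with 91 and 453 counts in the melatonin libraries, and stood at -1.20 without untreated library 1 and -4.79 without melatonin library 2. It lost its call in DESeq2 and with a robust dispersion. SERPINB3 and SERPINB4 are near-identical paralogs, and GAS6-AS1 lies antisense to GAS6 with the strand setting of the counts not given in the sources used here.

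Autophagy, lysosome, SREBP2 and LXR lists did not pass camera with melatonin. With fry, the SREBP2 list (adjusted p = 0.0109, downward) and the LXR list (adjusted p = 0.0301, upward) passed, and the lysosome list did not (adjusted p = 0.434). Of 57 autophagy genes, 22 rose and 10 fell, also adjusted over the list alone (median 0.13, adjusted p = 0.0506). The list passed without untreated library 2 (adjusted p = 0.0432), melatonin library 1 (adjusted p = 0.0467) or melatonin library 2 (adjusted p = 0.0415), within a range over 12 alternatives of 0.0145 to 0.237, while fry gave adjusted p = 0.00209. CCPG1, an ER-phagy receptor, rose by 1.12, RB1CC1 by 0.63, TAX1BP1 by 0.50, MAP1LC3B by 0.38 and SQSTM1 by 0.29, and BNIP3 fell by 0.71 and BECN1 by 0.25. With the GC offsets RB1CC1 stood at 0.40 and SQSTM1 at 0.50, and with library totals only BECN1 stood at -0.15. ULK1 stood at -0.18, but at 0.18 past the threshold with the GC offsets, at -0.12 without a call without untreated library 2 and at -0.08 without a call with library totals only. GABARAPL1 (0.00, adjusted p = 0.983) did not pass, nor did ATG5 (0.11, adjusted p = 0.145), which passed at 0.19 without untreated library 2. Of 71 lysosome genes, 21 rose and 26 fell, or 22 and 26 adjusted over the list alone (adjusted p = 0.724), with NEU1 at 0.77, GPNMB at -0.70, CD63 at -0.67, CTSD at -0.60 and LAMP1 at -0.16. CTSD stood at -0.23 with the GC offsets, and LAMP1 at -0.07 without a call with library totals only. Of 28 SREBP2 targets, 5 rose and 15 fell, also adjusted over the list alone (median -0.15, adjusted p = 0.0539). The list passed without untreated library 1 (adjusted p = 0.0216), chloroquine library 2 (adjusted p = 0.0490) or melatonin library 2 (adjusted p = 0.0398), within a range over 12 alternatives of 0.00584 to 0.524. SREBF2, which encodes SREBP2, fell by 0.74, FDPS by 0.72 and FDFT1 by 0.40, and SQLE rose by 0.15 (0.24 with library totals only). Of 15 SREBP1 targets, 4 rose and 8 fell, also adjusted over the list alone (median -0.18, adjusted p = 0.0249, adjusted p = 0.341 with an estimated correlation), with FASN and FADS2 both at -0.93 and FASN at -0.54 under the GC offsets. ABCG1 rose by 1.62 and ABCA1 by 0.78 in a list of 8 LXR targets with 4 up and 3 down, also adjusted over the list alone (adjusted p = 0.290).

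Cholangiocyte markers fell with melatonin, and matrix genes went in both directions. Of 11 cholangiocyte and progenitor markers, 8 fell and none rose, also adjusted over the list alone (median -0.76, adjusted p = 1.17e-08, adjusted p = 0.115 with an estimated correlation), with MUC1 at -1.72 and KRT7 at -1.25. The 8 measured hepatocyte genes included KRT18 (-1.12), KRT8 (-0.82) and HNF4A (-2.06, from only 141 counts over the 6 libraries), which fell, and none rose. The same counts held adjusted over the list alone (median -0.20, adjusted p = 0.00906, adjusted p = 0.201 with an estimated correlation), although the median was 0.03 with the GC offsets. With chloroquine 3 of these 8 fell, or 4 adjusted over the list alone (median -0.36, adjusted p = 0.00195, adjusted p = 0.141 with an estimated correlation), and both calls of this list were lost without the count filter. Of 35 epithelial-mesenchymal and matrix genes, 11 rose and 17 fell, also adjusted over the list alone (adjusted p = 0.0506), with TIMP3 at -1.38, COL5A1 at -1.22, TGFBI at -1.16 and ITGA5 at -0.72. This list passed without untreated library 1 (adjusted p = 0.0443), untreated library 2 (adjusted p = 0.0103), chloroquine library 1 (adjusted p = 0.0485) or chloroquine library 2 (adjusted p = 0.0477), within a range over 12 alternatives of 0.0103 to 0.314, while fry gave adjusted p = 0.00226.

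In all, 8782 genes changed with melatonin, 4307 upward and 4475 downward, of which 1310 changed at least 2-fold (638 up, 672 down), and the median size of the change was 0.44 (log2). The count was 1197 (499 up, 698 down) when tested against a 1.5-fold change, and the 1310 with at least 2-fold were 818 in that test and 587 at a mean count of at least 50. With the GC offsets 8166 genes were called, and of the 8782 calls 6647 kept theirs and 65 turned direction. With library totals only, the median of all genes shifted from 0.01 to 0.10 and the calls from 49.0% to 61.7% upward (5541 up, 3434 down), so small changes are relative to that scaling.

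**Figure D3:**
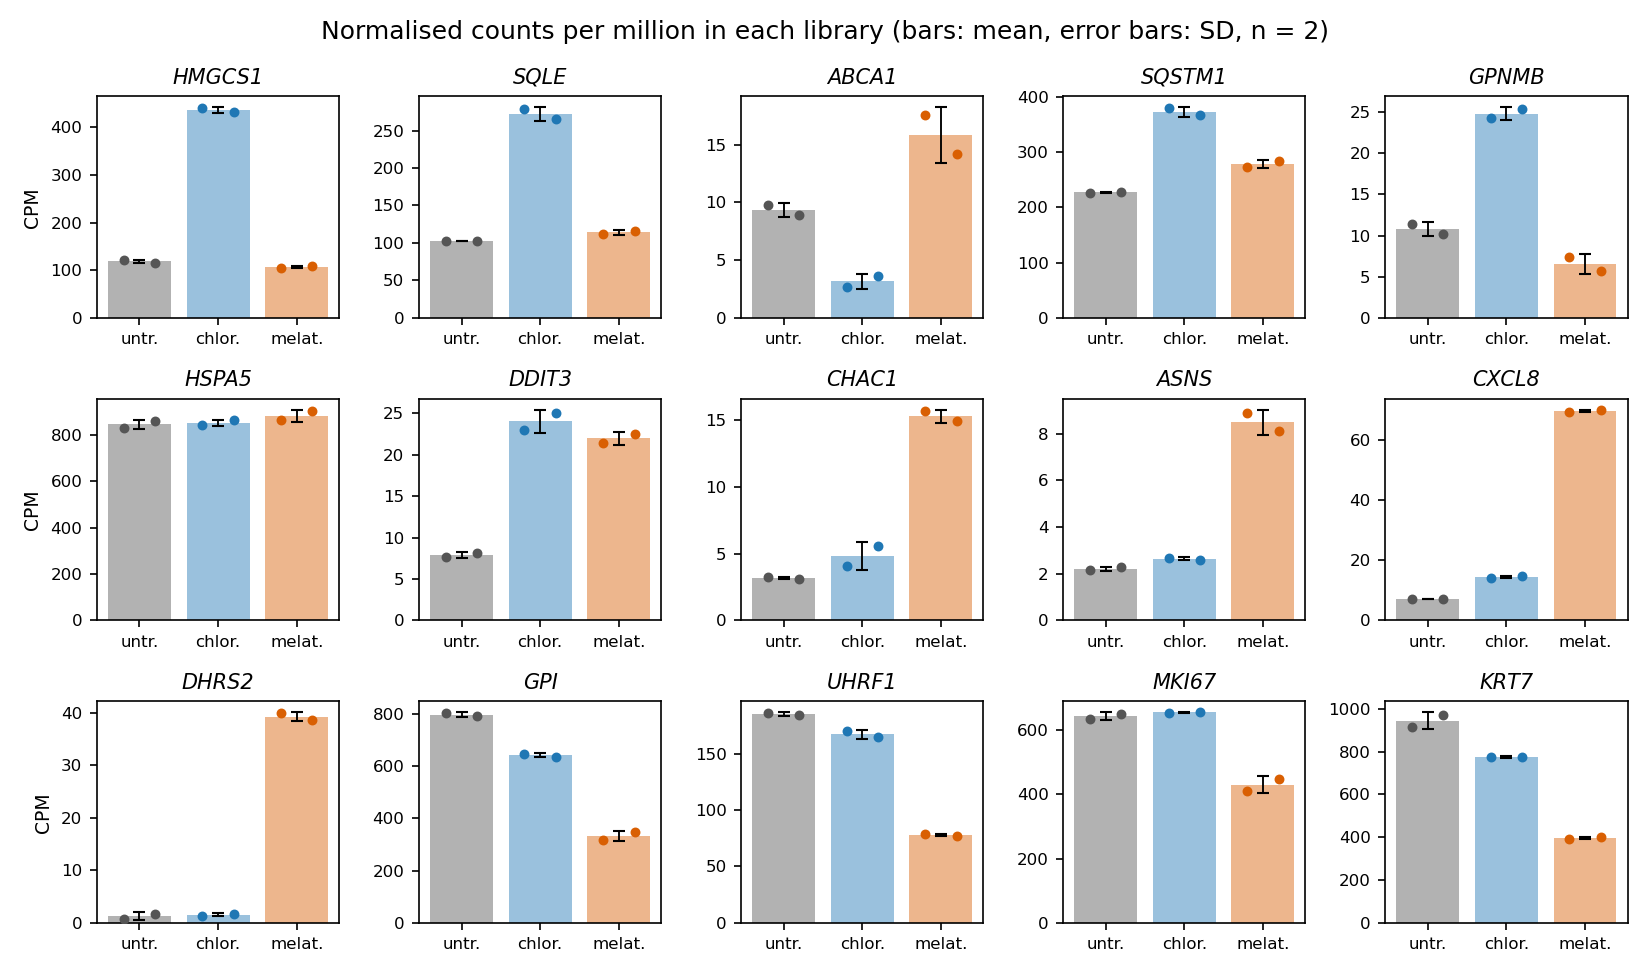
Normalised CPM of 15 named genes in the untreated (untr.), chloroquine (chlor.) and melatonin (melat.) libraries, with bars for the mean, error bars for the SD (n = 2) and a point for each library. HMGCS1 rises from 119 to 436 CPM with chloroquine, CHAC1 from 3.17 to 15.3 CPM with melatonin, and HSPA5 stays between 844 and 882 CPM in the group means.

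The direct comparison of chloroquine with melatonin asked where the effects of the agents differ. SREBP2 targets were higher with chloroquine, 25 of 28 higher and 1 lower, or 25 and 2 adjusted over the list alone (median 1.03, adjusted p = 2.81e-82, adjusted p = 0.102 with an estimated correlation). HMGCS1 was 4.10-fold higher with chloroquine and ABCG1 stood at -3.33 ± 0.16. Glycolysis genes (28 higher, 1 lower, or 29 and 1 adjusted over the list alone, median 0.59, adjusted p = 1.48e-35, adjusted p = 0.102 with an estimated correlation) and replication genes (36 higher, 0 lower, also adjusted over the list alone, median 0.44, adjusted p = 3.24e-23, adjusted p = 0.158 with an estimated correlation) were higher with chloroquine as well. The PERK and ATF4 list was lower with chloroquine, 6 higher and 28 lower, or 7 and 29 adjusted over the list alone (median -0.25, adjusted p = 3.00e-08, adjusted p = 0.102 with an estimated correlation). CHAC1 (-1.67) and ASNS (-1.69) followed this direction, while DDIT3 (0.13 ± 0.09, adjusted p = 0.218) and HSPA5 (-0.05 ± 0.03, adjusted p = 0.258) did not pass, which does not show that the agents act alike on them, and HSPA5 passed at -0.14 with library totals only. GPNMB (1.90), CTSD (0.97) and SQSTM1 (0.42) were higher with chloroquine, in a lysosome list of 31 higher and 14 lower, or 32 and 14 adjusted over the list alone (adjusted p = 0.0620). That list passed without untreated library 1 (adjusted p = 0.0418), untreated library 2 (adjusted p = 0.0414) or chloroquine library 2 (adjusted p = 0.0222), within a range over 12 alternatives of 9.73e-04 to 0.334, and its median fell from 0.09 to -0.00 with library totals only. Fry gave adjusted p = 0.00451 for the lysosome list, upward. By the naming rule, SERPINB3 (3.49), SERPINB4 (3.25), PDE2A (2.98), CCN5 (2.68) and BIRC7 (2.58) stood highest, and DHRS2 (-4.64), ABCG1, AREG (-3.25), CRISPLD2 (-3.06) and CLDN1 (-2.65) lowest. In all, 7933 genes differed, 4041 higher and 3892 lower with chloroquine, of which 1020 differed at least 2-fold (491 higher, 529 lower). The 1020 were 626 in DESeq2, 396 at a mean count of at least 50 and 518 when tested against a 1.5-fold difference. The count of 7933 was 755 in that test, and with library totals only the higher share moved from 50.9% to 36.3% (2952 higher, 5177 lower).

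Genes called under both agents mostly moved the same way. DDIT3, NR4A3 (1.04 and 1.65), CXCL8, PTGS2 and DUSP4 (0.99 and 1.09) rose with both, and EIF3CL (-1.45 and -1.62), ALPI, LY6D (-1.11 and -2.33) and TNFSF10 (-1.08 and -1.52) fell with both. H19 was called lower with both as well, with the spread between libraries and the lost calls given above. Of the 3413 chloroquine calls, 2314 (67.8%) were also called with melatonin in the same direction, 952 upward and 1362 downward, and 333 were called in opposite directions. Of all tested genes, 52.0% were called with melatonin. Independent lists of these sizes would share 889 genes in the same direction and 887 in opposite directions, which does not allow for the shared untreated libraries. ABCG1, ABCA1 and MYLIP (-0.85 and 0.53) fell with chloroquine and rose with melatonin, as did OCEL1 (-0.51 and 0.77) and ZNF846 (-0.51 and 0.71). OCEL1 lost its chloroquine call with the GC offsets (-0.34), and ZNF846 lost its own without untreated library 1 (-0.48), untreated library 2 (-0.54) or chloroquine library 1 (-0.33). ZNF114 (1.11 and -0.90), IGFL1P1 (0.89 and -1.49), IGFL2-AS1 (0.79 and -1.18), SERPINB3 (0.78 and -2.71) and ROS1 (0.74 and -1.04) rose with chloroquine and fell with melatonin, where IGFL2-AS1 is an antisense gene that depends on the strand setting. Both comparisons share the untreated libraries, so their fold changes covary without any effect. Across genes, which are not independent replicates, the covariance was 0.114, against 0.0343 to 0.0422 in 20 simulations with no effect, while the correlation of 0.482 lay under the 0.497 to 0.553 of the same simulations. With each agent set against a different untreated library the covariance was 0.0817 and 0.0772 and the correlation 0.263 and 0.252, with 1511 and 1587 genes shared in the same direction. The count of 2314 was 1373 in DESeq2, 19 when tested against a 1.5-fold change, 1082 with the GC offsets and 1406 without chloroquine library 2.

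**Figure D4:**
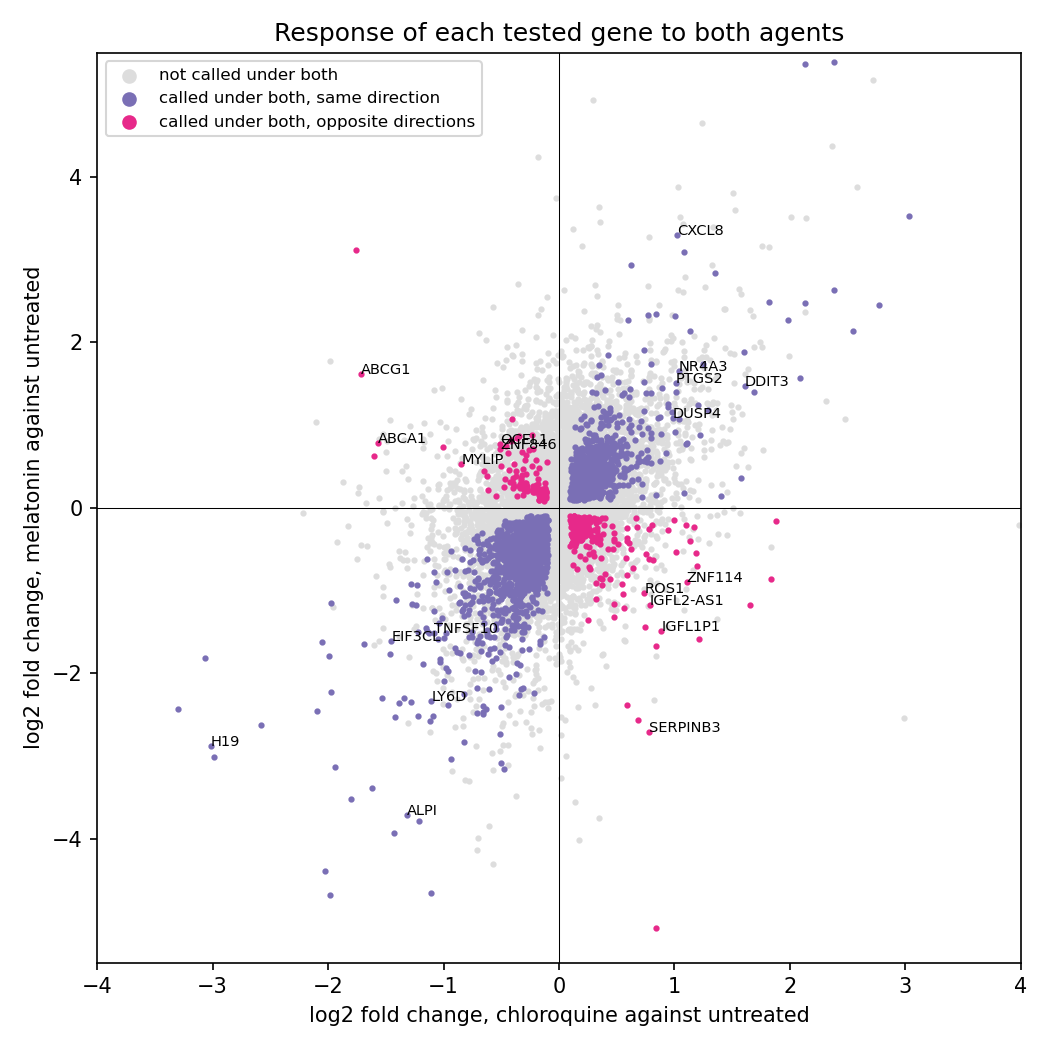
Log2 fold change with chloroquine (x axis) against that with melatonin (y axis) for each of 16877 tested genes, 4 of which lie outside the axes, in grey where not called under both agents, violet where called in the same direction (2314 genes) and pink where called in opposite directions (333 genes). Genes named by the rule for both agents carry their symbol, with DDIT3 and CXCL8 at upper right and ABCA1 and ABCG1 at upper left.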

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

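The GC and length offsets, equal depth, the offsets with the block and separate untreated libraries were chosen after the data were seen, and the other alternatives before. Counts of changed genes stayed within 1.5 times their value with RLE factors, upper-quartile factors, library totals only, limma-voom, a robust dispersion, no count filter, a mean count of at least 50, only the 2 groups compared and equal depth. The chloroquine count of 3413 was 2025 with DESeq2, which gave no adjusted p to 5236 tested genes, 1821 with the GC and length offsets and 1902 with the replicate block with these offsets. The count of 2314 genes changed in the same direction by both agents was 1373, 1082 and 1123 in the same order. Tested against a 1.5-fold change, which asks for larger effects by construction, 47 genes were called with chloroquine, 1197 with melatonin, 755 between the agents and 19 with both. With a library left out, the chloroquine count ran from 1974 (without chloroquine library 2) to 3732 (without melatonin library 1) and was 2249 without chloroquine library 1, and the shared count ran from 1406 to 2388. The melatonin count ran from 7570 to 8666 and the count between the agents from 6375 to 8076. Of the 36 list tests of a comparison, 18 with chloroquine, 16 with melatonin and 18 between the agents were called. With an estimated correlation camera called 1, 0 and 0 (12, 9 and 13 at an unadjusted p under 0.05), and fry called 23, 28 and 27. The estimated correlation comes with a test on 3 degrees of freedom, so the drop does not measure correlation between genes. ULK1 with melatonin turned from -0.18 to 0.18 with the offsets and to 0.18 with the replicate block and the offsets, and CDKN1A from -0.09, which was not called, to 0.14 and 0.13. Apart from the offsets, where their construction removes a trend that goes with the groups, the cause was not tested. With the replicate block alone 3436, 8731 and 7878 genes were called, all 108 list results kept their side of the threshold, and 313 of 315 values of named genes did. Of these values 286 kept their side and direction with the offsets, 299 with library totals only and 297 of 309 with DESeq2. Of the 108 list results, 102 kept their side of the threshold with the offsets. At this depth and with 2 libraries per group, 72.3% of genes changed 1.5-fold were called in the simulated chloroquine comparison, which does not separate depth from the number of libraries, and at equal depth 3159 genes were called with chloroquine.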

Other observations

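Tests with the offsets, with separate untreated libraries, at equal depth, of hepatocyte genes near 0, of HOX genes and of tubulin genes were chosen after results were seen, while the list tests, the test of GC slopes between libraries and the simulated test of shared controls were written before. The list of ribosomal proteins, fixed as a technical sign, was lower with both agents. Of its 73 genes, 1 rose and 42 fell with chloroquine, or 2 and 49 adjusted over the list alone (median -0.13, adjusted p = 6.30e-14, adjusted p = 0.141 with an estimated correlation), with RPL13 at -0.38. With melatonin 67 fell and none rose, or 68 and 0 adjusted over the list alone (median -0.35, adjusted p = 1.97e-23, adjusted p = 0.115 with an estimated correlation). Of 45 nuclear genes of oxidative phosphorylation, 17 fell and none rose with chloroquine, also adjusted over the list alone (median -0.08, adjusted p = 1.46e-05, adjusted p = 0.140 with an estimated correlation), with COX8A at -0.44 (-0.26 with the GC offsets). These numbers of called genes, like those of the ribosomal list, are without the offsets. Of 31 proteasome genes, 1 rose and 18 fell with melatonin, also adjusted over the list alone (median -0.14, adjusted p = 0.00554, adjusted p = 0.237 with an estimated correlation), with PSMB7 at -0.45. With chloroquine 1 rose and 10 fell, or 1 and 11 adjusted over the list alone (adjusted p = 0.0477, adjusted p = 0.286 with an estimated correlation). That call was lost without untreated library 2 (adjusted p = 0.120), chloroquine library 1 (adjusted p = 0.0622) or chloroquine library 2 (adjusted p = 0.0677), within a range over 12 alternatives of 0.00218 to 0.286. Of 11 cholangiocyte markers, 1 rose and 5 fell with chloroquine, or 1 and 6 adjusted over the list alone (median -0.29, adjusted p = 2.74e-04, adjusted p = 0.140 with an estimated correlation), with SOX4 at -0.49. Of 19 circadian genes, 7 rose and 1 fell with chloroquine, also adjusted over the list alone (median 0.21, adjusted p = 0.00975, adjusted p = 0.148 with an estimated correlation). With melatonin 6 rose and 7 fell (adjusted p = 0.609), and NR1D2, a clock repressor, rose by 0.55 with chloroquine and by 1.36 with melatonin.

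Iron genes gave 4 up and 7 down of 15 with melatonin, or 5 and 7 adjusted over the list alone, with camera pointing down (adjusted p = 0.0246, adjusted p = 0.214 with an estimated correlation), a mean of -0.17 and a median of 0.06, which was -0.07 with the GC offsets. FTH1, the ferritin heavy chain, fell by 1.04 and TFRC, the transferrin receptor, fell by 0.85. Of 25 genes of phosphoinositides and sphingolipids, 16 rose and 2 fell with melatonin, also adjusted over the list alone (median 0.23, adjusted p = 0.00296, adjusted p = 0.166 with an estimated correlation), with CERS6 at 0.90. Of 6 nuclear-retained RNAs, a sign of RNA fraction or intronic reads, 3 rose with chloroquine and 1 with melatonin, and none fell, or 4 and 1 adjusted over the list alone (adjusted p = 5.39e-04 and 0.0136, adjusted p = 0.141 and 0.227 with an estimated correlation). With melatonin the call was lost with the GC offsets (adjusted p = 0.0641, range over 12 alternatives 0.00276 to 0.227). NEAT1 rose by 0.44 with chloroquine and by 1.20 with melatonin. With all libraries the other lists did not pass camera with either agent, although fry called some of them, such as interferon genes with both. Their camera adjusted p with chloroquine and melatonin were as follows. NRF2 targets gave 0.174 and 0.863, interferon genes 0.154 and 0.766, apoptosis genes 0.800 and 0.265, and YAP targets 0.831 and 0.951. Fatty acid oxidation gave 0.189 and 0.825, metallothioneins 0.480 and 0.863, and melatonin receptors and metabolism 0.906 and 0.861. Mitochondrially encoded RNAs gave 0.412 and 0.749, non-polyadenylated RNAs 0.800 and 0.189, fibroblast markers 0.185 and 0.226, and endothelial markers 0.906 and 0.852. Lists that did not pass can still hold called members in both directions. Of 6 measured genes of melatonin receptors and metabolism, 3 rose and 1 fell with melatonin, and 0 were called with chloroquine. NQO2, a member of this list fixed in advance, stood at -0.55 in chloroquine against melatonin (edgeR adjusted p = 4.22e-07). The mitochondrially encoded list passed with chloroquine without untreated library 2 (adjusted p = 0.0205, range over 12 alternatives 0.0205 to 0.837). Lists that passed with 1 agent gave 0.160 for heat shock, 0.288 for iron and 0.255 for phosphoinositides with chloroquine, and 0.150 for p53 and 0.609 for endosomes with melatonin. Of the leukocyte markers 2 were measured, which is too few for a test, and of the red blood cell markers 0. Between the agents, mitosis genes (30 higher, 0 lower, median 0.34, adjusted p = 1.13e-15, adjusted p = 0.130 with an estimated correlation) and heat shock genes (14 higher, 3 lower, median 0.24, adjusted p = 1.15e-05, adjusted p = 0.130 with an estimated correlation) were higher with chloroquine. Immediate early genes were lower (5 higher, 22 lower, median -0.61, adjusted p = 2.24e-07, adjusted p = 0.102 with an estimated correlation).

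Most of the 3413 changes with chloroquine were small, and fold changes fell by 0.135 (log2) per 10% GC. As the cause of all of them the trend is argued against, since with offsets 1821 genes were called and 1361 of the 3413 kept their call, while the offsets moved other genes. GC trends that vary from library to library are argued against by a largest slope of 0.0179 between libraries of a group, and differences in library totals by 88.5% of the calls kept in the same direction at equal depth. For the 2052 calls lost with offsets (60.1%), whose median size went from 0.23 to 0.10 while the median SE stayed at 0.06, a trend made in the preparation of the libraries and an effect of chloroquine cannot be told apart, because the trend goes with the group. The same holds for the 2135 melatonin calls not kept with offsets (24.3%, median size from 0.28 to 0.09).

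Changes shared by both agents, 2314 in the same direction, have the untreated libraries in common. Independent variation of the single untreated libraries as the whole of the pattern is argued against. The covariance of 0.114 lies above the highest of 0.0422 in simulations with no effect, and was 0.0817 and 0.0772 with a separate untreated library for each agent. The simulations draw each library independently, and separate libraries keep what both untreated libraries have in common. A deviation common to both untreated libraries can therefore not be told apart from a response to both treatments. The correlation of 0.482 lies under the simulated 0.497 to 0.553, and does not decide because changes of a single agent lower it too. A GC trend as the whole of the pattern is argued against by a covariance of 0.0947 with the offsets, or 0.0635 and 0.0589 with the offsets and separate untreated libraries. A response common to both treatments may remain, as a hypothesis found and tested on the same data. Other sources common to the treated libraries, or to both untreated libraries, were not tested.

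Hepatocyte genes lay near 0 in all 6 libraries, with 8 of 43 measured. Too few reads are argued against by 78.6% of the cholangiocyte and progenitor markers being measured in the same libraries. A loss of liver genes in this line and cells of another origin than the label names cannot be told apart, since no genotype or reference profile is among the tables. Of 16 posterior HOX genes, chosen after the values were seen, 93.8% were measured, and CDKN2A at 115 CPM and STK11 at 1.07 CPM (means of the 2 untreated libraries) were noticed then as well. No biological explanation was tested, and the identity of the cells, on which the reading of every comparison depends, stays open.

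A hypothesis formed after the values were seen is that alpha and beta tubulin genes fall together with melatonin. Of 11 measured, 8 fell and 1 rose (median -0.62), which includes the 3 members first seen and is no test. Without those 3, 5 of 8 fell and 1 rose (median -0.38), and camera of limma with an estimated correlation returned 0.0498, at the edge of its threshold of 0.05. With the offsets the same 8 genes gave 4 down and 2 up (median -0.09) and 0.153, which did not pass, so the result depends on leaving the GC trend in. With chloroquine 3 of the 8 fell and none rose (median -0.17), and the test returned 0.0727, or 0.388 with the offsets.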
